A study of Mus musculus with 4 samples.

How the data were processed

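The series held Visium spatial expression of 4 brain libraries from female C57BL/6 mice, 1 library for each pairing of age (young, 3 to 4 months; aged, 18 to 20 months) with gavage (vehicle, or ethanol at 3 g/kg). Per the labels, animals received 10 exposures over 18 days, and tissue was taken 18 hours after the last one and cut at 10 µm. The deposited matrix held UMI counts of 32285 genes in 11064 spots, with a list of barcodes and a list of features, and it was used without rescaling. Per the file headers, the matrix was written by Space Ranger 1.3.1, whereas the processing notes of the authors named version 2.0.0 and the mm10 genome. Which version made the counts was not stated. The labels also did not state the annotation release, whether reads were subsampled when the libraries were combined, or whether the spots were limited to tissue. The letter after each barcode was tied to a library through the sample descriptions. Of the genes, 9538 had no UMI, and 38 symbols shared by more than 1 Ensembl identifier were kept apart.

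The libraries labelled young vehicle, young ethanol, aged vehicle and aged ethanol held 2743, 2889, 2784 and 2648 spots, with a median of 18733, 19046, 15119.5 and 16141 UMIs and of 5134, 5179, 4590 and 4628 genes per spot. Summed over a section, 3 UMIs stood for 0.0568, 0.0515, 0.0652 and 0.0623 CPM (counts scaled to the same total in each library) in the same order. Spots with fewer than 500 UMIs (27, 8, 81 and 6) were left out of the analysis, and 10942 were kept. No doublet caller was used, because a Visium spot covers several cells.

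Counts were scaled to 10000 per spot, log-transformed, and centred and scaled within each library. Clustering used 1605 features: 1500 variable genes from odd positions of the feature list, joined by those genes of 17 marker lists (119 genes) that were detected. Members of the gene lists and ribosomal, mitochondrial and haemoglobin genes were kept out of the variable genes. From 30 principal components a graph of 15 neighbours was built, and Leiden clustering at resolution 1 gave 32 clusters. After clustering, 10 clusters that served the planned comparisons were given a region name from their leading genes and marker lists. The other 22 were left without a region name, although some, such as those of choroid plexus, habenula, meninges and some white matter and cortical spots, also matched a marker list. Regions are therefore groups of spots with similar expression, not outlines drawn on an image. The planned comparison of a hippocampal neuropil region with the CA1 region was not made, because the candidate cluster carried more dentate than neuropil markers among its leading genes. That cluster was called the Cabp7-C1ql2 region after a pair of its leading genes.

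Regions were compared within each library by the log2 ratio of summed counts in CPM. A gene differed when the ratio was at least 2-fold in the same direction in each of the 4 libraries, with at least 20 UMIs over both regions in each. These comparisons used 16301 genes that took no part in clustering: members of the gene lists, and genes at even positions that were not markers. A zero was replaced by 3 UMIs, which turns the ratio into a bound. Among printed genes such a bound entered the median in 1 or 2 libraries for Ccn3, Gpr161 and Crhbp in dentate against CA1, Efcab6 in CA3 against CA1, Sspo, Sptbn5 and Oprk1 in white matter, and Cort and Crhbp in thalamus. Shares of spots were given with exact Clopper-Pearson 95% intervals.

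Age and gavage labels were compared over the whole section and within regions. With 1 library for each pairing of age and gavage, a comparison within an age or within a gavage label had no replicate, so no p-value was computed. A model of gavage with age as a second term would leave 1 residual degree of freedom over the 4 libraries, and it was not fitted. Ratios were given with exact conditional binomial 95% intervals, and a rule of size was applied: at least 2-fold, with at least 50 UMIs in the library with more. Counting noise was measured from 20 Poisson draws in which both libraries had the same expected value. The median log2 ratio of the genes tested moved by 0.091 at most when mitochondrial genes were left out of the total or when median-of-ratios size factors were used.

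There were 30 gene lists of cell types and pathways with 419 genes, 418 of which were found. Each list was described by the number of members that met the rule and by its median log2 ratio. In the group comparisons that median was also placed among the medians of 10000 random lists matched on mean expression. That placement describes these libraries and is not a test between animals.

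Named genes followed a rule: in region comparisons the 5 highest and 5 lowest by the library closest to 0, with up to 4 differing members per list. Between libraries it named 10 genes of all and 10 list genes with the widest range over the section and in the hippocampal regions. To these were added Gfap, C4b, Serpina3n, Apoe, Trem2, C1qa, Tlr4, App, Mapt, Ripk3, Mlkl, Bdnf, Fos and Xist. Clustering, cutoffs, lists, region comparisons and the naming rule were set before the data were examined. The rule was extended after values were seen to neocortex, white matter, thalamus and hypothalamus, to list members that met the rule of size, and to genes that met it in both ages. Alternatives for the group comparisons were also chosen after values were seen: other scalings, thinning of each spot to 5000 UMIs, a minimum of 100 UMIs, and clustering at resolution 0.6, at 1.6 or without centring. Alternatives planned earlier for the region comparisons included 30 neighbours, a spot minimum of 2000 UMIs or none, a gene minimum of 5 or 100 UMIs, a 1.5-fold cutoff and leaving out 1 library at a time.

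The rules were tested on simulated data with 50 genes planted at each size. Counts were drawn with Poisson noise around the pooled share of each gene, so differences between animals, planes and sections did not enter. The false calls given here thus reflect counting error alone. Between regions, 3-fold differences were recovered for 82% to 98% of planted genes and 4-fold ones for 96% to 100%, with 0 false calls. Between libraries, over the section, the hippocampal regions, neocortex and white matter, 98% to 100% were recovered at 3-fold and 100% at 4-fold, with 0 to 8 false calls per comparison and none in the wrong direction. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Gene coordinates came from the supplied mm10 tables.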

Results

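The 4 brain sections held 1 library for each pairing of age and gavage, and they shared their main regions but not their level in the brain. After spots with few UMIs were left out, 2716 spots remained in the library labelled young vehicle, 2881 in young ethanol, 2703 in aged vehicle and 2642 in aged ethanol. Mitochondrial transcripts made up 13.8%, 14.3%, 13.6% and 16.5% of UMIs. The sum of Lars2, Gm42418 and AY036118, which are often read as signs of ribosomal RNA carry-over, was 0.296%, 0.280%, 0.212% and 0.564%. The section labelled aged ethanol therefore differed from the others in RNA make-up before any gene was compared. Xist, the transcript of the silenced X chromosome, was present in each library at 36.6, 43.4, 37.9 and 50.3 CPM (counts scaled to a fixed total per library), and it was the 1 measured gene of the 5 in the sex check list.

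Clusters with the genes of CA1, CA3, dentate granule cells, upper and deep neocortex, white matter, thalamus and hypothalamus were found in each library. Thalamic spots made up 7.40% (6.44% to 8.45%) and 7.81% (6.82% to 8.88%) of the sections labelled young and aged vehicle. In those labelled young and aged ethanol they made up 15.9% (14.6% to 17.3%) and 17.7% (16.2% to 19.2%). The named white matter cluster held 8.17%, 7.95%, 8.66% and 10.6% of spots in the order young vehicle, young ethanol, aged vehicle and aged ethanol, and the hippocampal regions held 9.02%, 9.89%, 11.4% and 10.9%. The named neocortex clusters held 12.7%, 12.2%, 9.54% and 9.05%, with 6.55%, 6.28%, 3.88% and 3.71% in the upper one and 6.11%, 5.94%, 5.66% and 5.34% in the deep one. Some clusters left without a name also carried white matter markers or cortical genes, so these shares are not those of the whole tissue, and with such clusters added they would differ. A habenular cluster led by Gpr151, Tac2 and Pou4f1 had 29 and 21 spots in the libraries labelled ethanol and 0 in those labelled vehicle. The choroid plexus cluster, led by Ttr, had 25 and 24 spots in the libraries labelled vehicle against 12 and 13 in those labelled ethanol. The plane of section thus followed the gavage label, and each comparison of gavage below is also a comparison of planes.

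**Figure D1:**
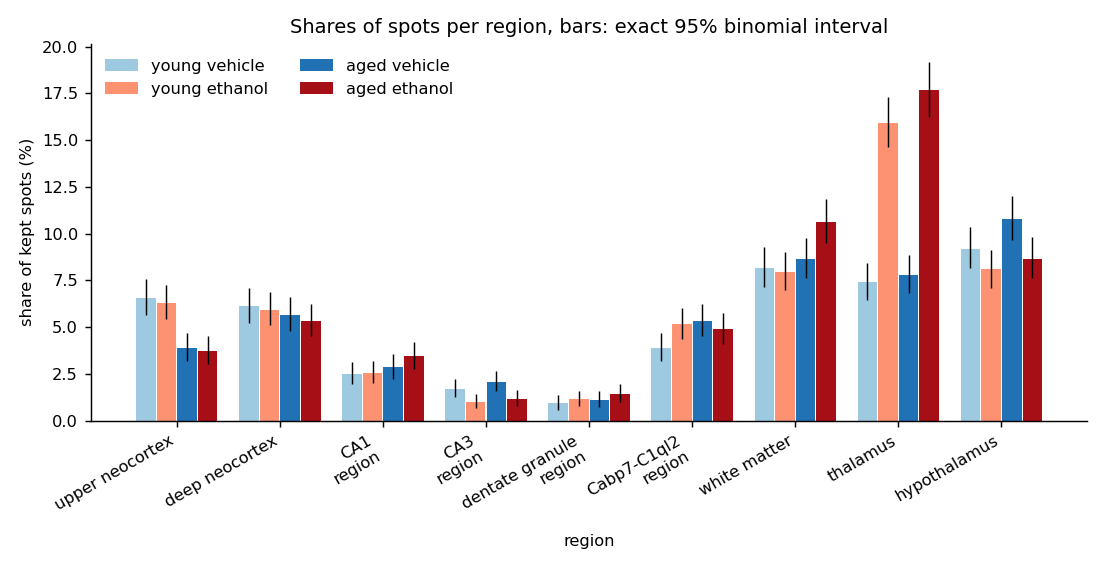
Share of kept spots (%) in each named region for the 4 libraries, with exact 95% binomial intervals as bars. Thalamus held 7.40% and 7.81% of spots in the libraries labelled vehicle and 15.9% and 17.7% in those labelled ethanol.

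Spots of the dentate granule and CA1 regions differed in some receptor, peptide and activity genes. The dentate region carried more kainate receptor transcripts and more Pdyn, the precursor of an opioid peptide, and Sox11 and Neurod1, from the neurogenesis list, were also higher there. CA1 carried more of the immediate early genes Arc, Egr1 and Nr4a1. Of 4780 genes tested, 152 were higher in the dentate region and 111 lower, and 1058 met the cutoff in some libraries but not in each. The highest were Tspan18 (median log2 ratio 4.08, 4.02 to 5.34 over the libraries), Gm34567 (3.84), Spata13 (4.09), Plekha2 (3.38) and Pdyn (3.60), which encodes prodynorphin. The lowest were Ptpru (−4.75, −5.51 to −4.46), Ccn3 (−5.20), Gpr161 (−4.06), Man1a (−4.49) and Gm2115 (−4.40). Among 13 measured members of the list of ionotropic glutamate receptor subunits, 3 were higher in the dentate region and 0 lower, namely the kainate subunits Grik4 (2.09), Grik3 (1.93) and Grik2 (1.25). The neuropeptide Y receptor Npy1r was higher (2.22), whereas the serotonin receptor Htr1a (−1.89) and Crhbp (−3.72), which binds corticotropin-releasing hormone, were lower. Of 12 immediate early genes 1 was higher, Btg2 (2.11), and 3 were lower: Nr4a1 (−3.40), Egr1 (−2.94) and Arc (−3.24). Of 16 postsynaptic density genes 3 were lower, the scaffold genes Homer2 (−2.61), Homer1 (−1.78) and Shank1 (−1.47), and 13 met neither cutoff. In the adult neurogenesis list 2 of 4 measured genes were higher, Sox11 (2.10) and Neurod1 (1.90). Some genes from lists made for inflammation, cell death or vessels also differed between these regions, and which cells of the spots carried them was not measured. Il1r1, the interleukin 1 receptor of an inflammatory list, was higher in the dentate region (3.21), as were Bbc3 (2.58), a cell death gene, and Ocln (2.20), a tight junction gene. Of 13 mitochondrially encoded genes 4 were lower in the dentate region, with mt-Atp8 and mt-Nd6 both at −2.11, and 0 of 20 nuclear oxidative phosphorylation genes met the cutoff.

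CA3 and CA1 were closer to each other. CA3 carried more of some transcripts of synaptic vesicle release, such as Syn2 and Snap25, and CA1 carried more Penk, the precursor of the enkephalins. Of 4794 genes 74 were higher in CA3 and 77 lower. Tspan18 (4.24), Tmem215 (4.11), Tmem114 (3.28), Grik4 (3.16) and Rerg (3.06) led the higher genes, and Ccn3 (−4.73), Ndst4 (−4.15), Kcnh7 (−3.80), Adgrl2 (−3.61) and Efcab6 (−3.41) the lower ones. Of 17 presynaptic genes 4 were higher and 0 lower: Vamp1 (1.51), Syn2 (1.49), Snap25 (1.33) and Cplx1 (1.32). The presynaptic Y2 receptor Npy2r was higher (1.84), while Penk (−3.05), Htr1a (−1.94), Nr4a1 (−1.97) and Egr1 (−1.33) were lower.

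Between the dentate and CA3 regions the opioid peptides set the regions apart. Pdyn (4.62, 4.05 to 5.98) and Penk (3.12, 2.09 to 4.30) were both higher in the dentate region, as was Npy1r (3.02), while Npy2r was lower (−1.68). Of 4423 genes 166 were higher and 86 lower. Spata13 (3.87), Plekha2 (3.72), Dgkh (3.38) and Pitpnm2 (3.36) were among the highest, and Cpne7 (−4.41), Kcnq5 (−3.85), Sv2b (−3.55), Klk8 (−3.41) and Thsd4 (−3.09) were the lowest. Gabrd, the subunit of extrasynaptic GABA-A receptors, was higher (1.97) and was the member that met the cutoff among 8 measured. Lpl, a lipase kept in the list of disease-associated microglia, was lower in the dentate region (−2.46). Which cells of the spots carried it was not measured.

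White matter differed from neocortex in complement, reactive astrocyte and some microglia and oligodendrocyte genes, which were higher, and in many genes of synapses, which were lower. Members of the complement, microglia and reactive astrocyte lists were among the genes higher in each library. Of 6098 genes 553 were higher in white matter and 925 lower. The highest were C4b (4.72, 4.69 to 5.44), the fourth complement component, which leads this cluster but took no part in forming it, Gfap (4.45), Sspo (4.63), D7Ertd443e (4.01) and A230009B12Rik (3.88). C4b lies on chromosome 17 at 34728139 to 34743902 and its near-identical neighbour C4a at 34809092 to 34823460, so reads may have been assigned to the wrong copy. The lowest were Sptbn5 (−4.95), Gm11549 (−4.48), Tmem215 (−4.38) and Igfbp6 (−3.81). In the microglia list 10 of 16 measured genes were higher and 0 lower (median 1.63), among them Ctss (2.29), C1qb (2.09), C1qa (2.01) and C1qc (1.98). For disease-associated microglia it was 7 of 12 with 0 lower (1.61), including Cd9 (3.45), Lyz2 (3.17) and Cd63 (2.26). Complement and antigen presentation had 6 of 7 higher (Cd74 2.56, H2-K1 2.07), and reactive astrocyte genes 6 of 7 (Vim 3.13, Cd44 2.30). Of 14 homeostatic astrocyte genes 2 were higher, including the water channel Aqp4 (2.28). The interferon list had 4 of 10 higher, with Ifi27l2a (3.00) and Ifitm3 (1.96), and the Toll-like receptor list 4 of 8, with Pycard (2.13) and Nfkbia (1.97). Oligodendrocyte precursor and differentiating genes were higher for 6 of 10: Enpp6 (3.91), Sox10 (3.69), Olig2 (3.30) and Bcas1 (3.26) are printed here.

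Some enzymes that clear ethanol products and oxidants were also higher in white matter than in neocortex, while more members of their lists met neither cutoff. Aldh1a1 (1.99), Aldh9a1 (1.53) and Cat (1.54) were the 3 of 10 ethanol metabolism genes that met the cutoff, with 0 lower and 7 neither. Of 16 antioxidant genes 6 were higher, with Nfe2l2 (2.25), the regulator of that response, and Nqo1 (2.20). On the lower side stood 9 of 11 GABA-A subunits, 7 of 15 glutamate receptor subunits (Gria3 −2.92, Grin2b −2.58), 14 of 18 presynaptic genes (Stx1a −3.76, Snap25 −2.96) and 15 of 16 postsynaptic genes (Homer1 −3.42, Nrgn −3.41). Lower too were 9 of 15 immediate early genes (Egr3 −3.55, Egr1 −3.40), 4 of 8 neurotrophin genes with Bdnf (−3.49), and 2 of 12 interneuron genes with Vip (−3.44). The receptor list had 6 of 15 lower, among them Crhr1 (−3.54), Oprk1 (−3.53) and Npy1r (−3.10). Of 16 amyloid list genes 2 were higher, Clu (1.42) and Aplp1 (1.37), 2 were lower, among them Cdk5r1 (−2.51), and 12 were neither. Hopx (1.79) was higher and Neurod1 (−3.91) lower in the neurogenesis list, Tnfrsf1a (1.52) was higher among 11 cell death genes, Cdkn2c (2.00) among 6 senescence genes, and Hsph1 (−1.42) was lower among 18 heat shock genes. None of 13 mitochondrially encoded, 20 nuclear oxidative phosphorylation, 14 endothelial, 8 pericyte or 4 erythrocyte genes met the cutoff.

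Thalamus and neocortex differed in genes such as Slc17a6 and Gbx2 and in cortical interneuron transcripts. Slc17a6, the vesicular glutamate transporter of subcortical neurons, was higher in thalamus (4.44), and so was the GABA transporter Slc6a11 (3.13). Of 6171 genes 286 were higher and 443 lower, led by Gbx2 (7.55), Cfap221 and Slitrk6 (both 6.66), Patj (5.53) and Mctp2 (5.45). Cortical interneuron transcripts were lower: Vip (−7.26), Sst (−4.81) and Npy (−3.35) were among 9 of 12 list members that met the cutoff, and Cort (−6.12) was lower as well. Crh (−5.10), Crhbp (−4.75) and the cannabinoid receptor Cnr1 (−3.78) were among the 9 of 15 receptor list genes that were lower. Of 11 GABA-A subunits 2 were higher (Gabra4 2.22, Gabrd 1.61) and 2 lower, including Gabra5 (−2.54). Aldh1a1 was higher (2.99, 2.83 to 3.29), the 1 higher of 10 ethanol metabolism genes, with 1 lower and 8 neither. Of 15 immediate early genes 9 were lower, with Egr3 (−5.04), Egr4 (−4.91) and Arc (−3.94).

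Hypothalamus was marked by Dlk1 (6.93), Gabrq (6.33), Arhgap36 (6.24), AW551984 (6.21) and Irs4 (5.29). Compared with neocortex 227 of 6222 genes were higher and 353 lower. Tbr1 (−7.28), a transcription factor of cortical projection neurons, Cort (−5.97) and the cortical glutamate transporter Slc17a7 (−5.09) were among the lowest. Slc6a11 (3.30), Slc17a6 (3.01), Tac1 (2.48) and the serotonin receptor Htr2c (2.33) were higher, as were C4b (1.59) and Apoe (1.17). Lower were 10 of 15 immediate early genes, 8 of 16 postsynaptic genes and 7 of 18 presynaptic genes.

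White matter of the libraries labelled ethanol carried more transcripts of C4b and of some microglia and reactive astrocyte genes, such as Trem2 and Serpina3n, than that of the libraries labelled vehicle, at both ages. The difference was wider between the libraries labelled young than between those labelled aged. Gpr17, a gene of differentiating oligodendrocytes, was lower. Each pairing of age and gavage stood for 1 library, so no comparison within an age had a replicate and no test was made. The intervals below cover counting error, not differences between animals, planes or sections.

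In the libraries labelled young, 100 of 6442 white matter genes met the rule of size with a higher value in ethanol and 77 with a lower value. In those labelled aged it was 86 and 49 of 6235. Counting noise alone gave a mean of 2.95 and 6.95 genes. At both ages 32 genes were higher and 8 lower, where 0.836 and 0.302 would have been shared by chance, and 3 went in opposite directions. Across genes, the ratios of both ages had a correlation of 0.40, with genes not being independent of each other. C4b stood at 96.6 and 1003 CPM in young vehicle and young ethanol, 10.4-fold (9.03 to 12.0), and 3.82-fold (3.34 to 4.38) higher in aged ethanol than in aged vehicle. Serpina3n, a protease inhibitor of reactive astrocytes, was 14.2-fold (10.7 to 19.2) and 6.05-fold (4.42 to 8.49) higher. Spp1, which encodes osteopontin, was higher by 3.90 and 2.68 in log2 (119 and 65.8 CPM in the libraries labelled ethanol). Spp1 was also a leading gene of an unnamed cluster led by Six3. That cluster had 18 and 4 spots in the libraries labelled vehicle and 40 and 32 in those labelled ethanol. Such tissue within the white matter spots is therefore not excluded for Spp1. Cst7, a protease inhibitor of activated microglia, rose from 2 to 77 UMIs and from 1 to 60. Trem2, the microglial lipid receptor, was 3.98-fold (3.19 to 5.02) and 2.48-fold (1.95 to 3.19) higher, and C1qa 3.20-fold (2.89 to 3.55) and 2.13-fold (1.89 to 2.42). Lyz2, Cd68, Cd52, Cx3cr1, Tyrobp, Vim and Ighm were among the other shared genes. Ighm, an immunoglobulin heavy chain, was 3.13-fold and 4.80-fold higher, while Igkc, a light chain, had 0, 1 and 0 UMIs in the first 3 libraries and 201 in aged ethanol. Ighm was also among the leading genes of the deep neocortex cluster, so it did not mark immune cells alone in these sections. Which cells of the spots carried it was not measured. Gfap met the rule in the libraries labelled young (2.01-fold, 1.86 to 2.18) and not in those labelled aged (1.28-fold, 1.18 to 1.38).

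**Figure D2:**
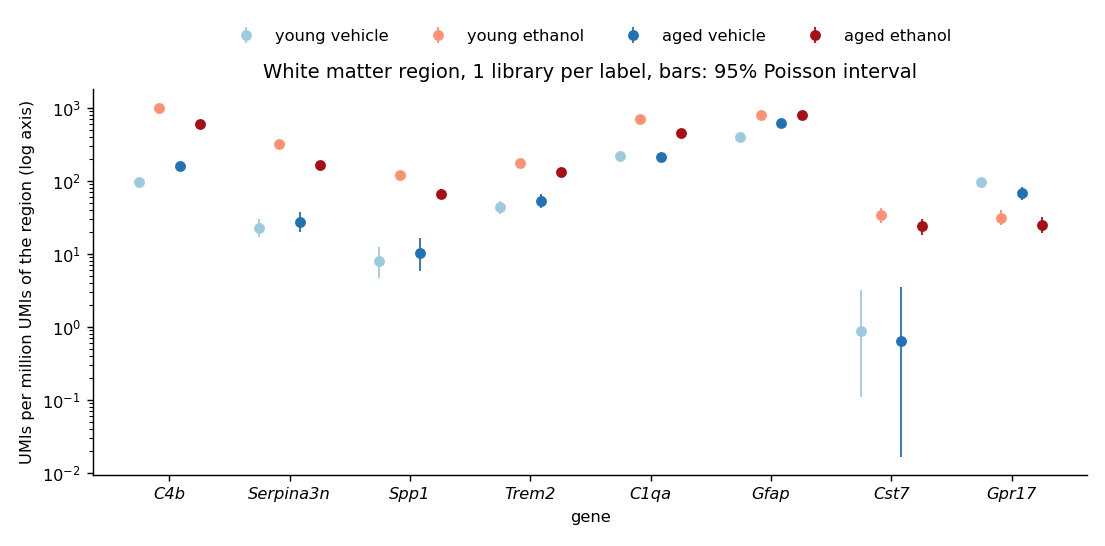
CPM (log axis) of 8 genes in white matter spots of the 4 libraries, with exact 95% Poisson intervals as bars. C4b stood at 96.6 in young vehicle and 1003 in young ethanol, whereas Gpr17 stood at 96.6 and 31.4.

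By list, 12 of 16 microglia genes met the rule in the libraries labelled young, with 0 lower and 4 neither (median log2 ratio 1.49), and 6 of 16 in those labelled aged, with 0 lower (0.82). Disease-associated microglia had 9 of 14 (1.52) and 5 of 14 (0.96), and reactive astrocytes 5 of 5 (2.35) and 2 of 5 (1.59). Complement and antigen presentation had 5 of 7 (1.61) and 1 of 7 (0.50), with C4b meeting the rule at both ages and Cd74 (4.49-fold and 1.41-fold), Psmb8 (3.57-fold and 1.29-fold), H2-D1 (3.06-fold and 1.83-fold) and B2m (2.23-fold and 1.70-fold) among the young. Homeostatic astrocyte genes had a median of −0.22 at both ages, and 0 of 14 met the rule. The antioxidant list had a median of 0.25 and 0.15 with 0 of 15 genes meeting the rule, and ethanol metabolism −0.11 and −0.23 with 0 of 8. The interferon list stood at 0.46 among the young and −0.00 among the aged, where Ifi27l2a was lower (−1.59). The Toll-like receptor list had medians of 0.15 and −0.11, with 1 and 0 of 5 genes higher. Heat shock and unfolded protein genes had 1 and 2 of 17 higher. Amyloid list genes had 0 and 1 of 16, the 1 being Mapt (2.13-fold, 1.87 to 2.43), which encodes tau. Mapt was not particular to white matter. It was also higher in aged ethanol than in aged vehicle in the dentate granule (1.74-fold), Cabp7-C1ql2 (1.56-fold) and CA3 (1.43-fold) regions. In deep and upper neocortex it was 1.69-fold and 1.57-fold higher. Aged vehicle held the lowest Mapt value of the 4 libraries in each of these regions. In the cell death list 1 and 0 of 4 were higher, and in the senescence list 0 and 1 of 4 lower, Cdkn1a (−1.09). Presynaptic genes had medians of −0.29 and −0.09, postsynaptic genes −0.24 and 0.03, glutamate receptor subunits −0.30 and −0.32, GABA-A subunits −0.29 and −0.10, and neurotrophin genes −0.21 and 0.04, and 0 members met the rule. Nuclear oxidative phosphorylation genes had −0.14 and −0.19, and mitochondrially encoded genes 0.13 and 0.47. Lars2, read as a sign of RNA make-up, was 2.19-fold and 3.75-fold higher. Haemoglobin genes moved in opposite directions: 3 of 4 erythrocyte genes were higher among the young and 4 of 4 lower among the aged. Endothelial genes had medians of −0.07 and −0.47, and 2 pericyte, 2 lymphocyte and 2 neurogenesis genes were measured, too few for a median.

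**Figure D3:**
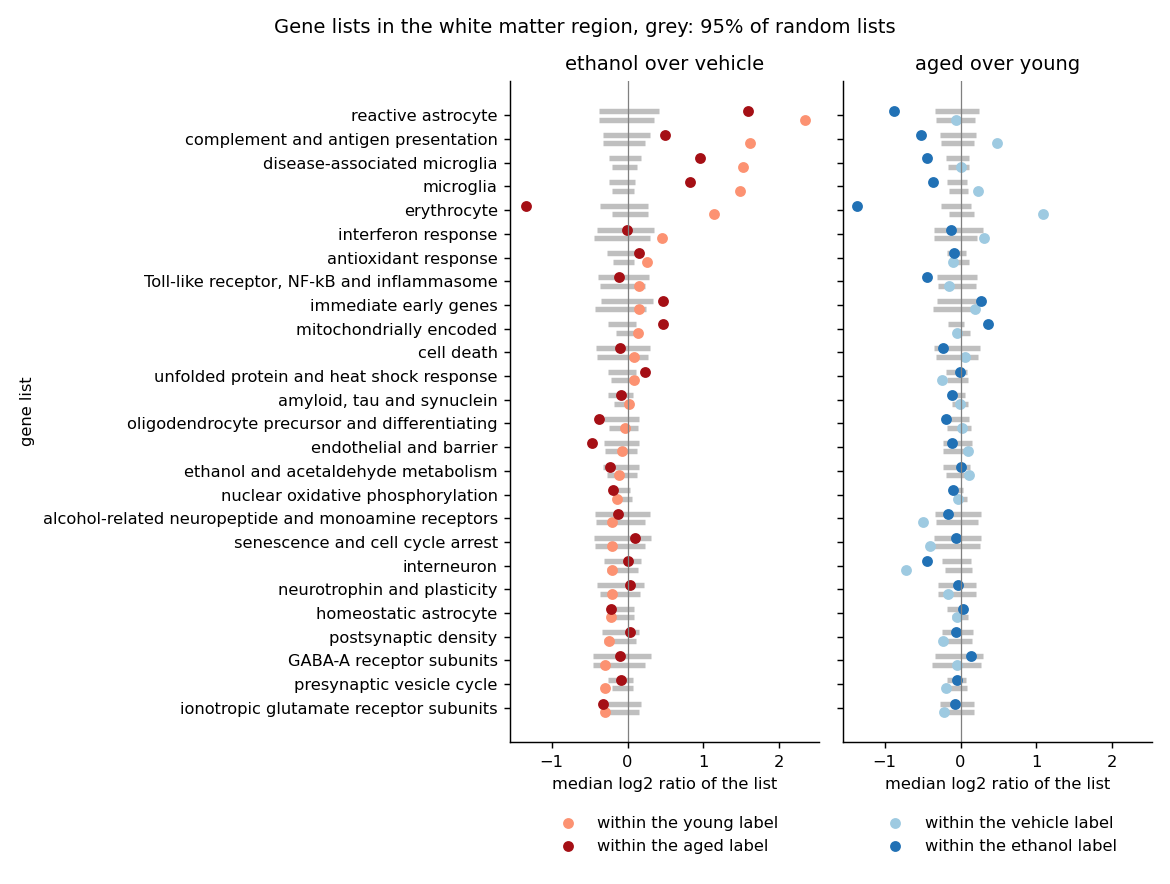
Median log2 ratio of 26 gene lists in white matter, ethanol over vehicle (left) and aged over young (right), with grey bars for 95% of expression-matched random lists. The microglia list stood at 1.49 and 0.82 on the left and at 0.23 and −0.36 on the right.

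Genes lower in white matter of the libraries labelled ethanol included Gpr17, Fabp7 and Myoc at both ages. Gpr17, a receptor of differentiating oligodendrocytes, was 3.08-fold (2.34 to 4.08) and 2.72-fold (1.97 to 3.78) lower. Fabp7, a fatty acid binding protein of glial progenitors, was 2.31-fold and 3.33-fold lower. Markers of other tissue moved in the same spots: Myoc (5.23-fold and 17.2-fold) and Igf2 (2.15-fold and 2.63-fold), which were among the leading genes of the cluster of meninges, were lower, and the hypothalamic peptide gene Pmch was 17.3-fold and 5.43-fold higher. In the oligodendrocyte list Gpr17 was the 1 of 9 members that met the rule at either age, with list medians of −0.03 and −0.38.

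Over the whole section, hypothalamic peptides set the libraries apart before any glial gene. Hcrt, the precursor of the orexins, had 33 and 69 UMIs in the libraries labelled vehicle and 15396 and 13340 in those labelled ethanol (423-fold, 301 to 614; 185-fold, 146 to 238). Its neurons lie in the lateral hypothalamus, and the count varied with the plane described above. Oxt (18, 1187, 233 and 4853 UMIs), Avp (107, 7372, 676 and 9650), Pmch (235, 27333, 6746 and 11183), Gm5741 (1, 378, 1 and 214), Prl, Gh, Qrfp, Nr5a1 and Igkc made up the other 9 of the 10 genes with the widest range. Among the libraries labelled young 179 of 14553 genes met the rule as higher and 139 as lower, and among those labelled aged 98 and 141 of 14268, with 59 higher and 60 lower in both. C4b was 4.86-fold (4.53 to 5.22) and 3.16-fold (2.95 to 3.38) higher, Cst7 by 3.81 and 3.31 in log2, Itgax 8.67-fold and 4.48-fold, and the chemokine Ccl4 6.79-fold and 6.32-fold. Serpina3n was 2.60-fold and 1.74-fold higher, Trem2 1.88-fold and 1.64-fold, C1qa 1.72-fold and 1.53-fold, and Gfap 1.70-fold and 1.37-fold. Apoe (0.10 and −0.05 in log2) and App (0.09 and 0.22) moved little. Lcn2, an acute phase gene, was higher among the young alone (20.8-fold, 12.8 to 36.1) and stood at 1.48-fold (0.839 to 2.65) among the aged. Tlr4 had 29, 30, 25 and 34 UMIs, Ripk3 6, 20, 8 and 2, and Mlkl 4, 11, 7 and 4, too few to describe. The lymphocyte list had 3 of 6 genes higher at both ages (0.87 and 1.04), and the reactive astrocyte list 4 and 1 of 11. The adult neurogenesis list had medians of −0.41 and −0.19, with Igfbpl1 at 62 and 18 UMIs in the young and 49 and 11 in the aged. The list of pericyte genes had medians of 0.09 and −0.28.

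In the hippocampal regions, complement C4b and immunoglobulin Ighm were higher in both libraries labelled ethanol, and some immediate early genes, such as Arc and Fos, were higher in aged ethanol. Among the libraries labelled young 41 of 9956 genes met the rule as higher and 11 as lower, and among those labelled aged 50 and 34 of 10182. At both ages 10 genes were higher and 3 lower. C4b was 4.49-fold (3.54 to 5.76) and 2.15-fold (1.76 to 2.63) higher, and Ighm, which is also a leading gene of the deep neocortex cluster, 3.52-fold and 5.64-fold. The largest C4b counts came from the Cabp7-C1ql2 region (46, 254, 83 and 151 UMIs), while in the dentate granule region C4b was 1.42-fold (0.692 to 3.06) and 2.17-fold (0.997 to 5.38) higher and in the CA3 region 6.11-fold (2.62 to 16.5) and 4.69-fold (2.32 to 10.1). Both of these regions held too few C4b UMIs for the rule to be met. Shox2, Synpo2 and Prkcd, genes with strong expression in thalamus, were also among the shared genes. Ttr, the transthyretin of the choroid plexus, was 7.06-fold (6.23 to 8.02) and 10.6-fold (9.42 to 12.1) lower, as were Nkd2 and Grp. Of 14 immediate early genes 5 met the rule as higher in aged ethanol against aged vehicle (median 0.70): Arc (2.87-fold, 2.46 to 3.36), Egr4 (2.41-fold), Fos (2.33-fold, 1.65 to 3.34), Egr1 (2.21-fold) and Nr4a1 (2.11-fold). In young ethanol against young vehicle the median was 0.01 and 0 of 14 met it, with Arc lower (−0.81). The interneuron peptides Vip (−1.96) and Tac1 (−1.57) were lower in aged ethanol. Microglia genes had a median of 0.42 among the young and −0.05 among the aged over the hippocampal regions together, and 0 of 15 met the rule. Within the CA3 region C1qa met it at both ages (2.25-fold, 1.58 to 3.22, and 2.05-fold, 1.46 to 2.90). Trem2 had 20, 14, 9 and 10 UMIs there, too few for the rule to be met. C1qa did not meet it in the dentate granule region (1.83-fold and 0.979-fold) or the Cabp7-C1ql2 region (1.45-fold and 1.27-fold). Over the hippocampal regions together Serpina3n stood at 0.11 and −0.07, so its rise in white matter was not seen there. Lars2 (1.09 and 1.41) and Gm42418 (1.02 and 1.20) were higher too. Bdnf stood at 49.4, 55.9, 46.1 and 55.6 CPM. No member of the GABA-A, glutamate receptor, ethanol metabolism or postsynaptic lists met the rule. Lcn2 had 1 and 71 UMIs in the libraries labelled young and 3 and 8 in those labelled aged.

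Neocortex followed the pattern of C4b (6.31-fold, 4.29 to 9.60; 3.77-fold, 2.59 to 5.61) and Lyz2 (2.72-fold and 2.21-fold), but few other genes were shared. Among the young 42 of 10759 genes were higher and 10 lower, among the aged 39 and 28 of 9842, with 5 higher and 1 lower in both, 4 opposite, and a correlation of −0.12 across genes. Gpr17 was the shared lower gene (2.33-fold, 1.67 to 3.28; 2.06-fold, 1.36 to 3.15), although its value in the aged was 0.071 in log2, of the opposite sign, when spots were thinned. Arc (−1.19) and Npas4 (−1.04) were lower in young ethanol, and stood at 0.36 and 0.10 among the aged. Penk (1.25) and the receptor Htr2c (1.32) were higher in young ethanol. Of 13 mitochondrially encoded genes 2 met the rule in aged ethanol, mt-Atp8 (1.42) and mt-Nd6 (1.17).

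Over the section, in white matter and in the hippocampal regions fewer genes met the rule between age labels than between gavage labels. In neocortex 62 did between aged and young ethanol, against 52 between ethanol and vehicle among the young. White matter of the library labelled aged vehicle had 12 of 6139 genes higher and 30 lower than young vehicle, and aged ethanol against young ethanol 26 and 33 of 6449, with 1 higher and 3 lower in both. C4b was 1.65-fold (1.37 to 1.99) higher in aged vehicle and 1.65-fold (1.54 to 1.76) lower in aged ethanol. Gfap was 1.56-fold (1.42 to 1.71) higher in aged vehicle, and Ifi27l2a, an interferon gene, 5.60-fold (3.93 to 8.14). Serpina3n was 1.92-fold (1.70 to 2.17) lower in aged ethanol, where the microglia list had a median of −0.36 against 0.23 within the vehicle label. Of 9 interneuron genes 2 and 3 were lower, with Sst 2.01-fold and 2.78-fold. Over the section 36 genes were higher and 15 lower within vehicle, and 25 and 46 within ethanol. Complement genes had a median of 0.33 within vehicle and 0.04 within ethanol. Lcn2 was 9.49-fold (6.68 to 13.9) lower in aged ethanol than in young ethanol, and Igkc 12.0-fold (9.62 to 15.1) higher. In the hippocampal regions 16 and 12 genes were higher and 1 and 17 lower, and Arc was 2.58-fold (2.22 to 3.02) higher in aged ethanol than in young ethanol. In neocortex 15 and 17 were higher and 13 and 45 lower. Crh was 2.58-fold (1.85 to 3.64) lower in aged ethanol, and Ttr 29.6-fold higher in aged vehicle, with the choroid genes Clic6 and Folr1 rising from 1 to 56 and from 2 to 57 UMIs beside it. Across white matter genes the aged over young ratios of both gavage labels had a correlation of −0.01.

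The sum of 6 newborn neuron genes was lower under the ethanol label at both ages, and whether it fell with the age label was not resolved. Dcx, Igfbpl1, Eomes, Draxin, Mki67 and Top2a, summed over the dentate granule and Cabp7-C1ql2 regions, had 44 UMIs in young vehicle, 9 in young ethanol, 40 in aged vehicle and 9 in aged ethanol. That was 16.4, 2.61, 12.5 and 2.65 CPM. Igfbpl1 made up 17, 3, 19 and 1 of these UMIs and Dcx 18, 6, 12 and 7. Among the aged the lower sum thus rested largely on Igfbpl1. The intervals of Dcx overlapped there (1.93 to 6.54 CPM in aged vehicle, 0.827 to 4.24 in aged ethanol). Aged over young, the ratio of the sum was 0.760 (0.483 to 1.19) within vehicle and 1.01 (0.356 to 2.88) within ethanol. In neocortex the same sum had 56, 94, 49 and 44 UMIs, but Dcx made up 49, 89, 42 and 43 of these, so it is a poor control for the sum in the hippocampal regions.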

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

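The expected values for the make-up of white matter, for exchanged labels, for choroid plexus markers with Kl, for depth and for the mitochondrial share were written before those tests were run. The tests of a response to ethanol and of choroid markers without Kl were chosen after results were seen.

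Some genes had ethanol over vehicle ratios that went in opposite directions in the libraries labelled young and aged. The aged minus young difference in log2 was −6.63 for S100a8, −3.27 for Xlr3b and −3.85 for Ghrh over the section. In neocortex it was −4.47 for Ttr, 3.35 for Gm42418, 3.29 for AY036118 and −2.22 for Apold1. In white matter it was −2.56 for Hba-a1, −2.41 for Hbb-bs and −2.97 for Hbb-bt. None of these differences was tested, because each pairing of age and gavage had 1 library. Ttr marks the choroid plexus and the haemoglobin genes mark red blood cells, so tissue and blood carried in the section may account for them, which was not tested.

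Some microglia, complement and reactive astrocyte genes were higher in the white matter of both libraries labelled ethanol (6 of 16 microglia genes, 1 of 7 and 2 of 5 met the rule among the aged). White matter of another make-up was tested as another mix of the finer white matter clusters alone. The microglia list kept a median log2 ratio of at least 0.86 within each of them. These clusters held 115 and 107 spots in young vehicle and 113 and 115 in young ethanol. In aged vehicle they held 131 and 101, and in aged ethanol 171 and 108. Their mix was thus close between the libraries and could hardly have made the ratios. The test could not show a difference in make-up within a cluster. Pmch was higher and Myoc and Igf2 were lower at both ages, so other tissue within these spots is not excluded. A response to ethanol (the smaller of the medians being 0.82, the other 1.49) cannot be told apart from an exchange of the labels young ethanol and aged vehicle, under which the ratios printed as gavage would be those of age. In the dentate granule and Cabp7-C1ql2 regions, newborn neuron genes, which fall with age in mice as a matter of background, had an aged over young ratio of 0.760 (0.483 to 1.19) within the vehicle label, while ethanol over vehicle was 0.159 (0.0683 to 0.330) among the young and 0.212 (0.0904 to 0.444) among the aged. Among the aged the ratio of ethanol over vehicle rested largely on Igfbpl1 (19 UMIs in aged vehicle, 1 in aged ethanol), while Dcx had 12 and 7. The pattern of the sum follows the gavage label, so the exchange stays a candidate explanation, as do ethanol and the plane of section. A marker of each animal's identity would be needed to decide.

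Ttr was lower in the hippocampal regions of both libraries labelled ethanol, and choroid plexus RNA in the hippocampal spots of the libraries labelled vehicle is a candidate explanation. Other choroid markers stood at 69.8 (58.3 to 82.9) per 1000 Ttr UMIs in those spots of young vehicle, against 12.6 in the choroid cluster. That count was mostly Kl, which had 107 to 114 UMIs in the hippocampal regions of each library and is also expressed by neurons, so the test was run again without it. Without Kl the value was 11.7 (7.40 to 17.6) against 8.03, and in aged vehicle 17.1 (12.8 to 22.4) against 7.87. The source of the Ttr transcripts cannot be told apart on these values, and a response to ethanol was not tested.

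In the hippocampal regions 5 of 14 immediate early genes met the rule as higher in the library labelled aged ethanol (median log2 ratio 0.70). Depth of the spots was argued against, since the median over the same 14 genes was 0.54 after thinning (first taken over the 7 genes that still reached the minimum, at 1.03, a set changed after that value was seen). Leaving the share of mitochondrial transcripts out of the total gave 0.71, which moves each gene by the same 0.017 by construction and so is no test of RNA quality. A response to ethanol in the aged, RNA quality, handling before tissue was taken and the plane of section stay open. The mix of hippocampal regions also differed between libraries, and its part in the median was not tested. The median was 0.01 among the young and −0.21 for aged over young within the vehicle label, so a lower value in aged vehicle also entered the ratio.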

How the results depend on the processing

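The alternatives for the region comparisons were set before the data were examined, whereas those for the age and gavage comparisons were chosen after the results had been seen. No test was made, and a model of gavage with age as a block, which would leave 1 residual degree of freedom over the 4 libraries, was not fitted. A 1.5-fold cutoff gave 615 genes in dentate against CA1 (263 at 2-fold), 338 in CA3 against CA1 (151), 643 in dentate against CA3 (252), 2426 in white matter (1478), 1278 in thalamus (729) and 1153 in hypothalamus (580), each of the last 3 against neocortex. With at least 100 UMIs the numbers were 106, 75 and 90 in the hippocampal comparisons, 482 in thalamus and 383 in hypothalamus, because fewer genes were tested by construction. Leaving out 1 library at a time gave 289 to 328, 166 to 174, 295 to 329, 1568 to 1699, 784 to 817 and 642 to 665, in the same order. The CA3 region did not form with 30 neighbours, without centring, without a UMI minimum or with at least 2000 UMIs per spot, so its comparisons had no value there. In the age and gavage comparisons, in the order ethanol against vehicle in young and aged and aged against young within vehicle and ethanol, at least 100 UMIs gave 195, 133, 32 and 40 genes over the section, and 17, 40, 2 and 7 in the hippocampal regions. It gave 24, 23, 12 and 23 in neocortex, and 71, 58, 11 and 23 in white matter. Thinning each spot to 5000 UMIs gave 118, 158, 25 and 44 over the section and 76, 80, 16 and 29 in white matter. In the hippocampal regions it gave 27 and 44 for ethanol and 12 for age within ethanol, and in neocortex 21, 33 and 38. Thinning dropped 23.9%, 17.9%, 31.2% and 14.6% of white matter spots in young vehicle, young ethanol, aged vehicle and aged ethanol. With those settings fewer genes reach the minimum by construction, and any other cause was not tested. The other scalings and clusterings kept the gene counts of the age and gavage comparisons within 1.5 times of those in the report over the section (scalings alone), in the hippocampal regions, in neocortex and in white matter. They were not run for thalamus and hypothalamus. Among genes that met the rule of size, the direction of 1 reversed: Gpr17 in neocortex of aged ethanol against aged vehicle stood at 0.071 in log2 after thinning. A change of sign in genes that did not meet the rule was not counted as a reversal. Of the values for genes named in those comparisons, 4652 of 5172 stayed within the counting interval and 519 moved out of it. The scalings without mitochondrial genes and with median-of-ratios factors kept 1124 and 1104 of 1144. They shift each gene of a comparison by the same small amount, so they could hardly show a change. Thinning, which redraws the counts, moved 383 of 1144 and reversed 1. For genes named between regions, 3865 of 4068 stayed within the spread of the libraries. Of these, the 271, 271 and 187 values with a 1.5-fold cutoff and minima of 5 and 100 UMIs reused the same ratios and could not move. Leaving out 1 library drops 1 of the 4 ratios behind the same median, and 271 of 271 stayed each time, so these settings could hardly show a change. Of the numbers of differing list members between regions, 241 of 2640 moved by more than 1.5 times. Of the ranges between libraries 41 of 217 moved out of the counting interval, and with regions weighted equally it was 17 of 28. Of the shares of spots, 90 of 136 stayed within their interval under other clusterings and 46 did not.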

Other observations

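The thalamus and hypothalamus were compared between labels after the other regions had been seen, and their genes were chosen for naming after values were known. Both regions held C4b, Serpina3n and Ighm at higher values in the libraries labelled ethanol, and Ighm is also a leading gene of the deep neocortex cluster. In thalamus C4b was 2.69-fold (1.83 to 4.09) higher among the young and 5.06-fold (3.17 to 8.56) among the aged, Serpina3n 4.43-fold and 4.17-fold, Ighm 5.40-fold and 3.25-fold, and the phagocytic gene Cd68 2.51-fold and 2.57-fold. Ifi27l2a was 2.29-fold and 6.14-fold higher, opposite in the aged to its white matter ratio. Gabra3, a GABA-A subunit, was 4.75-fold (2.95 to 8.11) and 3.09-fold (2.01 to 4.96) higher, and Syt2, a vesicle calcium sensor, 11.6-fold and 3.09-fold. Hcrt, Pmch and Pvalb were also among the 21 thalamic genes higher at both ages. Syt2 and Pvalb were leading genes of an unnamed cluster led by Six3. Other tissue or another plane within the thalamic spots is therefore not excluded for these ratios. Among the young 112 of 10393 thalamic genes met the rule as higher and 30 as lower, with counting noise giving a mean of 36.25, and among the aged 100 and 23 of 9454.

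In hypothalamus C4b was 7.42-fold (5.25 to 10.8) and 7.18-fold (5.20 to 10.2) higher, Gfap 3.55-fold and 3.81-fold, Serpina3n 2.74-fold and 2.18-fold, and Lyz2 2.56-fold and 4.27-fold. C1qa was 1.69-fold higher among the young and 2.33-fold among the aged, the reverse of the order in white matter. The peptide genes Trh (37.0-fold and 56.8-fold), Pdyn (20.4-fold and 6.00-fold) and Sst (5.53-fold and 2.15-fold) were higher, as was Th (4.57-fold and 3.13-fold), which encodes an enzyme of catecholamine synthesis, and Hdc (178 and 1 UMIs, 80 and 6 UMIs) was lower, which varied with the plane of section. Among the young 68 genes were higher and 55 lower, among the aged 83 and 42, with 32 higher and 13 lower in both.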
